A study of Homo sapiens with 8 samples.

How the data were processed

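The samples were 8 libraries of human cells labelled HepG2, a line described in the labels as hepatocarcinoma. They covered 4 treatments, each with an m6A immunoprecipitation (IP) library and an input library. Per the labels' protocols, polyA-selected RNA was fragmented to about 100 nt, precipitated with an anti-m6A antibody and sequenced from random-primed cDNA. Every group held 1 library, and no untreated sample was analysed here.

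The values came from a deposited table of 25918 gene models with UCSC-style identifiers, gene symbols and coordinates. For each treatment it gave an expression quantile and, for every m6A peak, its transcript position, exon number, exon length, transcript segment and score. Per the file headers, the peak score is the authors' own enrichment score. Its formula and log base were not given in the sources used here, and the lowest score in the table was 2. The aligner, peak caller, pooling of libraries and genome build were not given in the sources used here either. Of 17056 gene models whose symbol is in GENCODE 29, 99.7% lay on the same chromosome, but 0.0352% started within 1000 bases of the GRCh38 gene start. The coordinates are therefore not those of GRCh38, and they are printed as deposited, with the start counted from 1.

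The deposited expression quantile is a rank of the gene model within its treatment, written here as a percentile from 0 to 100. It holds no amounts and no read depth, so the depth of the libraries is unknown and no fold change can be given. The column names do not say whether the rank comes from the IP, the input or both. Gene models tied at the lowest rank formed a floor at percentile 45.5 for UV, 32.7 for heat shock, 20.4 for HGF and 18.4 for IFNg. For comparisons, values under the highest floor were raised to it.

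The design fixed before the data were examined assumed expression amounts and enrichment folds. The deposited units needed stand-ins, which were chosen after the table, including some of its values, had been seen. The low-value filter became a percentile of 60 or more in any treatment, which 12624 gene models passed. A 2-fold expression difference became 10 percentile points beyond the nearest of the other 3 treatments. Peaks of the same gene model with positions within 100 nt were joined into 1 site. Because scores were used only as ranks, a 2-fold enrichment difference became 25 points of score rank among the 2925 sites with a peak in all 4 treatments.

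No test across replicates was possible, and no p-value is given. For each of 17 gene lists fixed before the data were examined, the median shift against the median of the other 3 treatments was placed among 10000 random lists of the same size. Random lists were matched on mean percentile in 20 bins, and positions below 2.5 or above 97.5 were taken as standing apart. This describes these libraries only. With 17 lists in 4 treatments, some positions outside those bounds arise by chance. A gene with several models was represented by the model with the highest mean percentile. Shares of peaks carry exact Clopper-Pearson 95% intervals, which cover counting error only.

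The lists covered IFNg response, type I interferon response, heat shock response, DNA damage response, immediate early genes, HGF and MET-ERK response, hepatocyte genes, acute phase genes, m6A machinery, unfolded protein response, proliferation, cholesterol synthesis, replication-dependent histones, housekeeping genes, and blood-cell, fibroblast and endothelial, and cholangiocyte markers. Named genes followed a rule fixed before the data were examined. It took up to 10 members in each direction of a treatment's own lists that differed by 10 points or more from the median of the other 3. It also took the 5 highest and 5 lowest gene models and the 5 largest gains and losses of score rank, and always the m6A machinery. Models without a recognised symbol were not named, and some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen.

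GC content was taken from the longest GENCODE 29 transcript of the same symbol. Matching through current and older symbols covered 78.0% of gene models past the filter, under the 80% needed, with a rank correlation of -0.720. Matching was then extended to RefSeq synonyms, after that value had been seen, and covered 88.6%. A GC correction subtracted, in each treatment, the median of gene models in the same of 40 GC bins. This correction, and the rank counted from the top on a log2 scale, were added after the main list results had been seen and were applied to every list. The GC correction subtracts the same amount from genes near the top of a bin, where percentiles differ little. It can therefore create or remove shifts in top-ranked lists. The stop-codon peaks used the deposited segment labels. Motifs were not analysed here.

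Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data, in an easy setting. All treatments shared the same base level with small noise, and no GC or pair difference was simulated. In the data, expression ranks differed between treatments by medians of 3.33 to 8.64 points. Simulated sites were widely spaced with little jitter. The test therefore checks the calculation and does not measure false calls in these libraries. Of 200 gene models raised by 20 points among 25918, 200 were recovered and 0 others were called. All 600 simulated sites were recovered, and 6.5% of unchanged lists fell outside the 2.5 to 97.5 bounds.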

Results

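The transcriptome-wide distribution of N6-methyladenosine (m6A), the commonest internal modification of mRNA, was mapped in cultures labelled HepG2 under 4 treatments. UV irradiation was given at 0.04 J per square centimetre with 4 h of recovery, and heat shock at 43 degrees for 30 min. The recovery was recorded for UV alone, but it may also apply to heat shock. The remaining cultures received hepatocyte growth factor (HGF, the ligand of the MET receptor) at 10 ng/ml or interferon gamma (IFNg) at 200 ng/ml. No exposure time was recorded here for HGF or IFNg, so the response lists below are read without it. Each treatment had 1 IP and 1 input library, so no difference below has a replicate check. Expression is given as a percentile among 25918 gene models, and each treatment is set against the other 3. The depth of the libraries is unknown. Coordinates are as deposited, on a build not given in the sources used here.

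The deposited table listed 13307 m6A peaks after UV, 9803 after heat shock, 9111 after HGF and 5280 after IFNg. These lay in 7172, 5663, 5508 and 3556 gene models, respectively. Peaks were mostly in well expressed genes. Among gene models at the 90th percentile or above, 67.9% had a peak after UV, 56.5% after heat shock, 49.1% after HGF and 38.2% after IFNg. When peaks within 100 nt were joined, 17764 sites resulted, of which 2925 (16.5%) had a peak in all 4 treatments. Sites listed after a single treatment numbered 3730 for UV, 1599 for HGF, 928 for IFNg and 900 for heat shock, and 3084 were listed in 3 treatments. In the 6330 gene models with a mean percentile of 75 or more, these numbers were 2109, 1054, 759, 665 and 1853, with 2032 in all 4. Of heat shock peaks, 83.6% were matched by a UV peak, against 11.97% when positions were displaced by 400 nt. Of IFNg peaks, 72.6% were matched by an HGF peak, 67.8% by a UV peak and 65.9% by a heat shock peak. Numbers of peaks can follow depth, which is unknown, and a site missing from a list is not shown to be unmethylated.

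**Figure D1:**
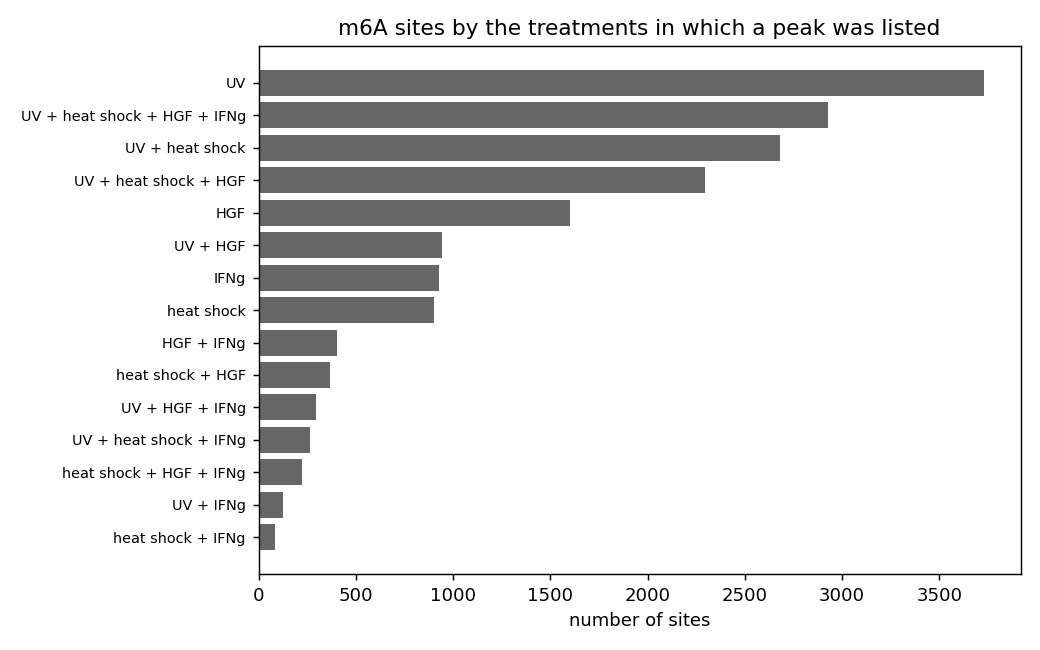
Number of m6A sites (x axis) for each combination of treatments in which a peak was listed (y axis). Sites listed after UV alone (3730) outnumber those listed in all 4 treatments (2925), and UV with heat shock (2678) exceeds HGF with IFNg (401).

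Coding sequence and the region around the stop codon held most peaks in every treatment. Around the stop codon lay 27.2% of annotated peaks after UV (95% interval 26.4 to 28.0), 27.4% after heat shock (26.5 to 28.3), 29.4% after HGF (28.5 to 30.4) and 28.96% after IFNg (27.7 to 30.2). The 3' UTR held 21.4%, 20.6%, 20.5% and 20.4%, and coding sequence 39.0%, 40.8%, 44.4% and 47.8%, in the same order. As a ratio between treatments, the transcript start share differed most. It held 9.49% of peaks after UV (8.99 to 10.0) and 8.47% after heat shock (7.92 to 9.05), but 3.85% after HGF (3.46 to 4.27) and 1.20% after IFNg (0.922 to 1.54). In gene models with a peak in all 4 treatments the start share was lower, at 5.34% for UV, 4.64% for heat shock and 2.08% for HGF.

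**Figure D2:**
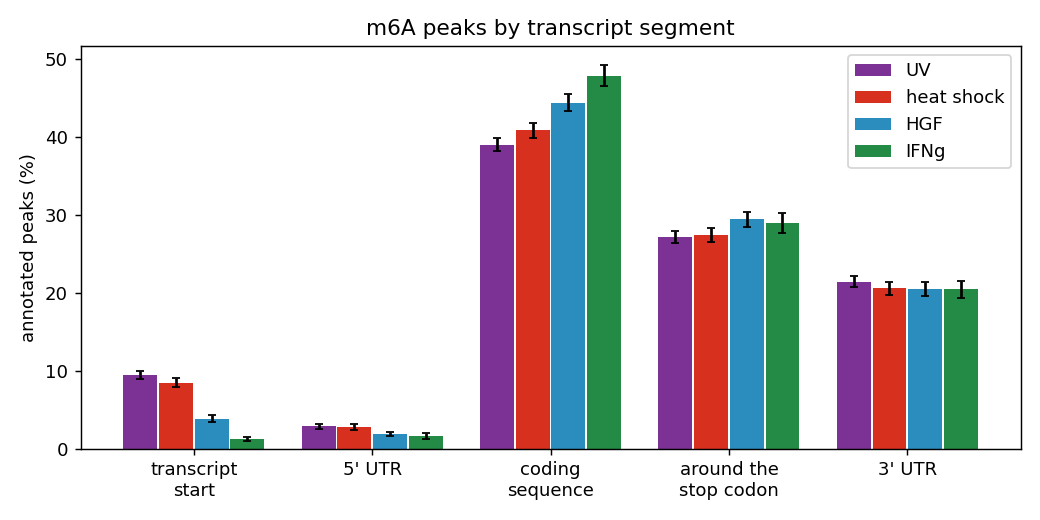
Percent of annotated m6A peaks (y axis) in each transcript segment (x axis) for the 4 treatments, with exact 95% intervals as error bars. The transcript start holds 9.49% of peaks after UV and 1.20% after IFNg, while shares around the stop codon lie between 27.2% and 29.4%.

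Interferon-response genes ranked far higher after IFNg than after any other treatment. The IFNg response and antigen presentation list had a median shift of 27.6 points over 39 genes, at percentile 100 of random lists. Of these, 28 lay at least 10 points above the median of the other treatments, 25 lay that far above all 3, and 0 lay 10 points below. IDO1, which degrades tryptophan, stood at the 98.98th percentile after IFNg and at 45.5, 32.7 and 55.6 after UV, heat shock and HGF. The guanylate-binding protein GBP1 (iduc001dmx.2, chromosome 1, 89290575 to 89303631, minus strand) stood at 96.0, against 48.2, 35.3 and 28.3. UBE2L6, the ISG15-conjugating enzyme, stood at 97.4, CD74, the invariant chain, at 97.2, and PSMB9, an immunoproteasome subunit, at 97.7. CIITA, the master regulator of MHC class II genes, stood at 86.8 and HLA-DRA at 88.2. GBP2, APOL1 and GBP5 stood at 95.03, 92.8 and 82.8. The type I interferon list had a median shift of 21.05 points over 37 genes, also at percentile 100. Of these, 29 lay 10 points or more above the median of the others and 0 below. Its leading members were IRF7, XAF1, IFI27, SAMD9L, SP110, IRF9, PARP9, IFI6, TRIM22 and OASL, with shifts from 43.2 down to 30.2 points. After GC correction the medians were 24.8 and 22.8 points, both at percentile 100. In the other treatments the IFNg list shifted by -1.93 points after UV (percentile 1.45), -4.16 after heat shock (0.220) and 0 after HGF (60.4), and the type I list by -3.45 (0.560), -0.749 (15.7) and -1.64 (13.6). The reference for these includes IFNg. Against heat shock alone and HGF alone, the IFNg list after UV shifted by 0.374 and -0.0733, and the type I list by -0.343 and 0.548, none standing apart. After heat shock the IFNg list shifted by -0.374 against UV alone and -2.09 against HGF alone, again not apart.

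Several of these transcripts carried m6A peaks listed only after IFNg. In the other treatments, GBP1, GBP2, GBP5, IDO1 and CIITA ranked under the 60th percentile. There, 18.4% of models above the floor had a peak after UV, 8.38% after heat shock and 6.28% after HGF. A missing peak can therefore follow from low rank, and methylation particular to IFNg is not shown. GBP1 had a peak at position 2683 in the 3' UTR, GBP5 at 2224 around the stop codon and GBP2 at 1842 in coding sequence. IDO1 had a peak at 1316 around the stop codon. CIITA had 3 peaks, at 1331 and 2544 in exon 11 and at 4379 in the 3' UTR. IRF1, a transcription factor of the pathway chosen after its values were seen, had 1 peak after IFNg and none elsewhere. It stood at 98.8 after IFNg and between 57.7 and 68.7 elsewhere. UBE2L6, CD74, PSMB9 and HLA-DRA had no peak in any treatment. Across the IFNg list, 16 of 39 genes had a peak after IFNg, against a median of 14 in random lists matched on expression (percentile 77.4). The numbers were 15 against 17 after UV (20.8), 9 against 13 after heat shock (6.75) and 7 against 13 after HGF (1.51).

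**Figure D3:**
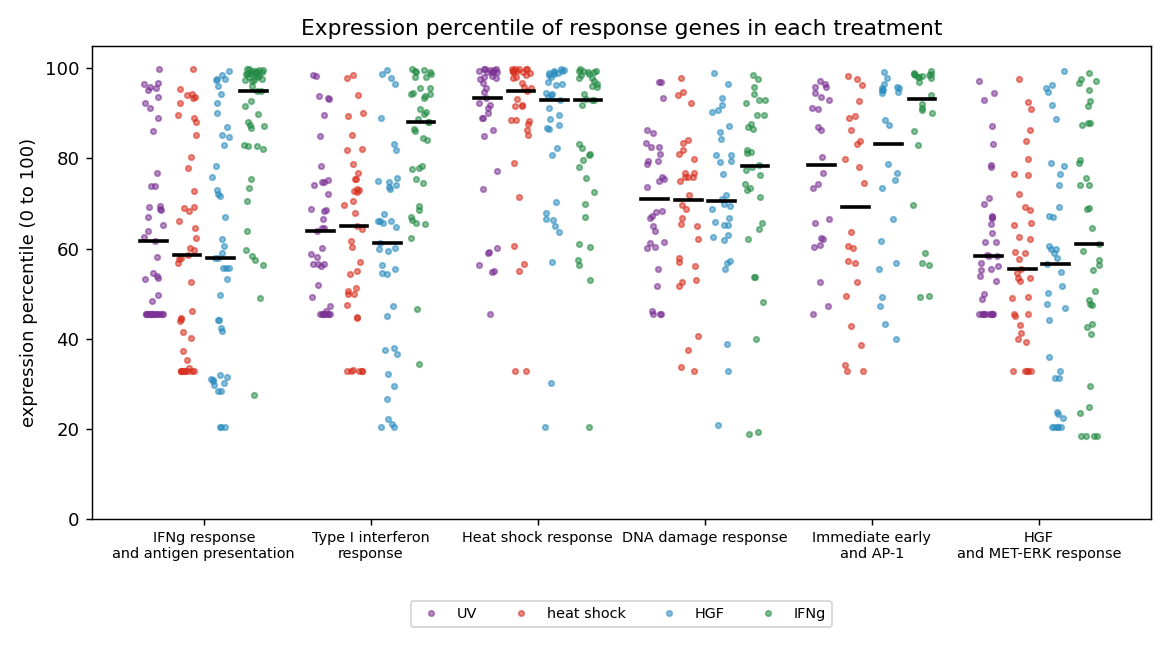
Expression percentile (y axis) of each gene (points) in 6 response lists (x axis) for the 4 treatments, with black bars at the list medians. The IFNg list has a median of 95.03 after IFNg and between 58.0 and 61.7 after the other treatments.

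Heat shock genes were near the top of the ranking in all 4 treatments, with list medians between 92.9 and 95.02. After heat shock the median shift over 34 genes was 0.889 points, at percentile 91.3 of random lists, so the list did not stand apart. Of these, 5 lay at least 10 points above the median of the others and 0 below. They were the co-chaperones DNAJB4 (92.0 after heat shock, 86.4, 67.8 and 56.4 after UV, HGF and IFNg) and CHORDC1 (96.8), the small heat shock protein HSPB8 (88.5), the transcription factor HSF2 (79.1) and the chaperone HSPA4L (98.0). Only 2, HSPB8 and HSF2, lay at least 10 points above all other treatments. CHORDC1 and HSPA4L stood at 91.9 and 94.8 after UV. Percentiles compress differences among the highest genes. On a log2 scale of the rank from the top, chosen after the main result was seen, the shift was 0.77 at percentile 100 after heat shock and -0.56 at 0.520 after IFNg. After GC correction, also chosen then, the heat shock value was 2.90 points at percentile 98.4. That correction can create shifts among genes near the top, so this value does not settle the question. A peak was listed in 27 of the 34 genes after heat shock, against 18 in matched random lists (percentile 99.9). After UV the count was 29 against 21 (99.9), after HGF 20 against 15 (94.9), and after IFNg 12 against 11 (66.8). DNAJB4 had peaks at positions 119 and 641 after heat shock, at 125 and 617 after UV, at 748 after HGF and none after IFNg. In the other treatments the list shifted by 0.600 points after UV (84.1), -0.704 after HGF (11.3) and -0.928 after IFNg (14.9).

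After UV, genes of the DNA damage response were not higher as a group. The list had a median shift of -0.957 points over 29 genes (percentile 21.6), with 0 genes at least 10 points above the median of the others and 7 below. Those below included GDF15, FDXR, BAX, SESN2, DDB2 and CDKN1A, but only 1, GDF15, lay that far below all other treatments. GDF15 was at the UV floor of 45.5, and SESN2 and CDKN1A ranked lower still after heat shock. With GC correction the list shift after UV was -0.0965 (43.1). CDKN1A, the cell cycle inhibitor p21, stood at 68.0 after UV, 57.0 after heat shock, 80.7 after HGF and 78.6 after IFNg. The same list had a median shift of -6.71 points after heat shock (percentile 0.160) and 4.20 after IFNg (98.5). GC-corrected values were -2.84 (1.06) and 2.84 (98.8). Neither call held against UV alone (-1.64 and 4.17) or HGF alone (-3.92 and 0.286). The shift after HGF was -0.444 (50.2), and 0.826 (67.2) with GC correction.

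Immediate early genes differed among the treatments in both directions. After UV the median shift was -1.06 points over 22 genes (percentile 9.77), which turned to 1.09 (81.2) with GC correction and stood apart at -0.28 (1.51) on the log2 rank scale. EGR3, JUN and CTGF lay at least 10 points above the median of the others, and NR4A1, FOS and EGR1 below. EGR1 stood at 76.8 after UV, 52.6 after heat shock, 95.6 after HGF and 98.6 after IFNg. FOS stood at 66.7, 38.5, 88.5 and 91.3. The list median shift was -6.24 after heat shock (0.0500) and 6.88 after IFNg (100). After HGF it was 1.00 (88.2), and -1.78 (8.92) with GC correction. The calls after heat shock and IFNg ended with GC correction, at -1.72 (8.46) and 1.48 (90.2). The list stood apart after UV and HGF against heat shock alone (4.60 and 6.24) and against IFNg alone (-4.67 and -3.32). Peaks were listed in 20 of the 22 genes after UV, 13 after heat shock, 15 after HGF and 17 after IFNg, against 13, 9, 9 and 7 in matched random lists. FOS and EGR1 had 3 and 4 peaks after UV, 0 and 0 after heat shock, 0 and 1 after HGF, and 1 and 2 after IFNg.

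The HGF and MET-ERK list did not stand apart after HGF against the other 3 treatments, with a median shift of 0.0733 points over 22 genes (percentile 62.7). Against IFNg alone it stood apart after HGF, at -6.24, and with GC correction the value against the other 3 was -1.35 (19.3). ETV4, an ETS factor downstream of ERK, stood at 79.0 after HGF and 74.1 after IFNg, against 45.5 and 45.4 after UV and heat shock. VEGFA stood at 94.8 after HGF and 96.9 after IFNg, against 83.2 and 84.0. EREG, DUSP5, HBEGF and DUSP4, all known targets of ERK signalling, lay at least 10 points below the median of the others. Only 1, EREG, lay that far below all other treatments. DUSP4 ranked higher after HGF (60.5) than after UV (45.5). DUSP5 (23.1) and HBEGF (44.1) were under the highest floor after HGF. The list shifted by 10.5 points after IFNg (percentile 100), where 12 genes lay at least 10 points above the median of the others, and by 7.31 (100) with GC correction. After heat shock the shift was -4.60 (2.13), which became -2.24 (3.79), no longer apart, with GC correction, and was not apart against UV alone (-1.28) or HGF alone (-3.58). After UV it was -1.39 (17.6).

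Among 12624 gene models past the filter, 428 ranked at least 10 points above all other treatments after IFNg and 381 ranked that far below. The numbers were 362 and 503 after heat shock, 244 and 274 after UV, and 198 and 176 after HGF. Small nucleolar and Cajal body RNAs filled most of the extremes. All 5 highest models after UV were such RNAs (SNORD92, SNORD45B, SNORD36B, SNORD8 and SNORD61), as were all 5 highest after HGF. Those 5 after UV were at the floor in every other treatment. The labels describe polyA-selected RNA fragmented to about 100 nt. How reliably such short RNAs were measured is therefore uncertain, and their ranks are not read as treatment responses. After IFNg, GBP1, SERPING1, the C1 inhibitor, and UBE2L6 were among the highest 5. TSPO, a mitochondrial outer membrane protein, was at the floor of 32.7 after heat shock and at 82.9, 94.1 and 96.8 after UV, HGF and IFNg. Another TSPO model at that floor had 1 m6A peak after heat shock. Gene models at the floor held 176 peaks after UV, 19 after heat shock, 4 after HGF and 1 after IFNg, so a floor value does not show that a transcript was absent. The scavenger receptor OLR1 stood at 57.2 after HGF and between 89.5 and 94.1 elsewhere. TREML2 was at the floor after UV and between 76.5 and 84.4 elsewhere. Among coding gene models chosen after their values were seen, CA9, a carbonic anhydrase, stood at 93.0 after HGF and between 67.8 and 72.3 elsewhere, and NDUFA5, a complex I subunit, at 45.7 after IFNg and between 70.2 and 92.1 elsewhere. With floors left as deposited, the share of higher among all shifted models moved from 41.8% to 31.9% for heat shock, from 52.9% to 33.2% for HGF and from 52.9% to 39.4% for IFNg. Re-ranking among models above the floor in all 4 moved it to 42.2% for IFNg and 43.2% for HGF. With the filter at the 90th percentile it was 8.04% for heat shock and 31.0% for HGF. At 5 points it was 42.7% for IFNg and 48.0% for HGF, and with GC correction 43.6% for HGF. Without the filter it turned from 47.1% to 56.3% for UV. Counting a 2-fold difference of rank from the top gave 69.1% for UV, 66.7% for HGF and 75.9% for IFNg. Of 195 small nucleolar and Cajal body RNA models past the filter, between 12 and 23 were higher and between 9 and 12 lower in each treatment.

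The treatments formed pairs that moved with GC content. Expression ranks correlated across gene models at a Spearman rho of 0.894 between UV and heat shock and 0.889 between HGF and IFNg. Across these pairs rho lay between 0.664 and 0.789. Gene models are not independent replicates. The difference between the pairs (UV and heat shock minus HGF and IFNg) correlated with transcript GC content at a rho of -0.717. Its median was 8.52 points at a GC content of 41.8% or less and -9.34 points at 56.5% or more. Within pairs, UV minus heat shock had a rho of 0.388 with GC, and IFNg minus HGF 0.241. After GC correction the counts higher and lower were 260 and 200 for IFNg, 181 and 189 for heat shock, 168 and 188 for UV, and 125 and 162 for HGF. The labels give no batch, so batch cannot be told apart from treatment.

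At the 2925 sites with a peak in all 4 treatments, a score rank apart from every other treatment was most common after IFNg. There, 223 sites ranked at least 25 points above all other treatments and 231 that far below. The corresponding numbers were 115 and 90 for UV, 99 and 85 for heat shock, and 93 and 108 for HGF. This count is lower for treatments whose scores go together, as for UV and heat shock. Against the median of the others, the numbers were 585 and 597 for IFNg and between 453 and 462 for the other treatments. Over all listed peaks, IFNg also had the lowest median score, 3.01 against 4.07 for UV, nearest the lowest listed score of 2. The largest gains after IFNg were in FRAT2, FEN1, ASXL1, GPR161 and C3orf38, and the largest losses in CELSR2, UBE3A, SLC39A6, PCYOX1 and DENND4A. The site of FEN1, a flap endonuclease, lay at position 2019 in the 3' UTR, with a score rank of 84.1 after IFNg and at most 10.6 elsewhere. After HGF the leading gains were in EGLN1, FOXO1, FEM1A, SLFN11 and YY1, and the losses in EIF2C2, BMI1, PDPK1, EMG1 and SH3PXD2A. EGLN1, an oxygen-sensing prolyl hydroxylase, had a score rank of 93.3 after HGF at position 4613 around the stop codon, and at most 21.4 elsewhere. After heat shock, gains were led by ADARB2, QRICH1, CDCA8, HRH1 and KLF5, and losses by CAMSAP1, CSRP2BP, EXTL2, TRAF3IP2 and ITGA6. After UV, gains were led by CTSB, L1CAM, IL27RA and GPR107, and losses by WDR20, TMEM79, ARRDC3, PCF11 and CDC2L5. Score ranks correlated at 0.690 between UV and heat shock, 0.524 between HGF and IFNg and 0.285 between heat shock and IFNg.

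The immediate early list also differed in score rank, over 10 sites. Its median shift was 41.6 points after IFNg (percentile 99.99), 18.8 after HGF (97.8), -18.8 after UV (2.19) and -22.5 after heat shock (0.670). With IFNg alone as the reference, the shift after HGF was -22.0 points. The UV call was lost against heat shock alone (-5.49) and HGF alone (-18.8), the heat shock call against UV alone (5.49) and the HGF call against UV alone (18.8). Score-rank shifts moved with GC content across sites, at a rho of 0.280 for IFNg and -0.233 for heat shock.

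Shifts of score rank and of expression were compared across the same sites. Input is the denominator of enrichment, so ranks taken from the input would give the correlation a built-in negative part. The score formula and the source of the ranks were not given, so the size of that part is unknown. Spearman rho was 0.228 for IFNg, 0.138 for heat shock, 0.00488 for HGF and -0.0593 for UV, and Pearson's r was 0.208, 0.118, 0.00393 and -0.0722. With both shifts GC-corrected, rho was 0.0382, -0.0554, -0.0613 and -0.119 in that order. In gene models with a mean percentile of 90 or more it was 0.303 for IFNg, 0.298 for heat shock, 0.108 for HGF and 0.0999 for UV, the last opposite in sign to the main value. Sites are not independent replicates. Of the 428 gene models higher after IFNg, 108 had a peak there, 18 of these only there, and 53 had a peak elsewhere but not after IFNg. Among the same 428, 133 had a peak after UV, 97 after heat shock and 99 after HGF. Of models higher after UV, heat shock and HGF, 37 of 244, 30 of 362 and 21 of 198 had a peak there. Only there it was 8, 0 and 5, and only elsewhere 5, 23 and 24.

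Of the 22 genes in the m6A machinery list, 20 were found by symbol, and these were well expressed in every treatment. METTL14 is not among the 20. The 20 members had median percentiles of 89.2 after UV, 89.3 after heat shock, 87.1 after HGF and 86.7 after IFNg, and list shifts between -1.71 and 1.07 points, at percentiles from 32.2 to 61.7. With GC correction all 4 shifts changed sign, from 0.492 to -0.809 after UV, 1.07 to -1.90 after heat shock, -0.901 to 1.47 after HGF and -1.71 to 0.247 after IFNg, and none stood apart. METTL3, the catalytic methyltransferase subunit, stood at 89.9, 82.6, 86.9 and 88.7, and WTAP at 92.9, 93.0, 82.6 and 87.5. KIAA1429 stood at 90.3, 91.6, 83.2 and 79.6, RBM15 at 90.7, 89.8, 94.4 and 91.6, and RBM15B at 87.4, 83.9, 90.4 and 90.6. CBLL1 stood at 77.0, 77.5, 81.5 and 86.0, and ZC3H13 at 89.3, 94.2, 88.2 and 85.1. The demethylase FTO stood at 84.9, 85.3, 82.7 and 76.3, and ALKBH5 at 90.5, 85.7, 94.5 and 96.5. Among the YTH readers, YTHDF1 stood at 89.1, 89.9, 87.4 and 91.3, YTHDF2 at 86.9, 90.8, 88.8 and 83.8, and YTHDF3 at 93.9, 93.2, 92.4 and 91.0. YTHDC1 stood at 85.8, 88.9, 78.8 and 82.3, and YTHDC2 at 84.9, 84.2, 75.4 and 72.1. ELAVL1, HNRNPA2B1 and HNRNPC stood after UV at 90.2, 99.7 and 96.0, and after IFNg at 84.8, 99.6 and 95.7. IGF2BP1 ranged from 81.5 to 90.02, IGF2BP2 from 69.8 to 79.6 and IGF2BP3 from 82.0 to 87.9. Of the 20 genes, 16 had a peak after UV, 16 after heat shock, 15 after HGF and 12 after IFNg, against 13, 11, 10 and 8 in matched random lists (percentiles 90.5, 99.3, 98.3 and 96.7).

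Liver genes were near the floor in all 4 treatments of the cultures labelled HepG2. The 36 hepatocyte genes in the table had median percentiles of 45.5, 32.7, 27.5 and 28.1 after UV, heat shock, HGF and IFNg, and between 31 and 33 of them were under the 60th percentile. ALB (albumin) stood at 45.5, 57.6, 24.9 and 22.3, and AFP (alpha-fetoprotein) at 45.5, 32.7, 20.4 and 22.4. CPS1, the urea cycle enzyme, was an exception, at 99.4 to 99.7. FOXA1 and CEBPA were above the 60th percentile in all 4. The housekeeping list had medians between 98.5 and 98.7.

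**Figure D4:**
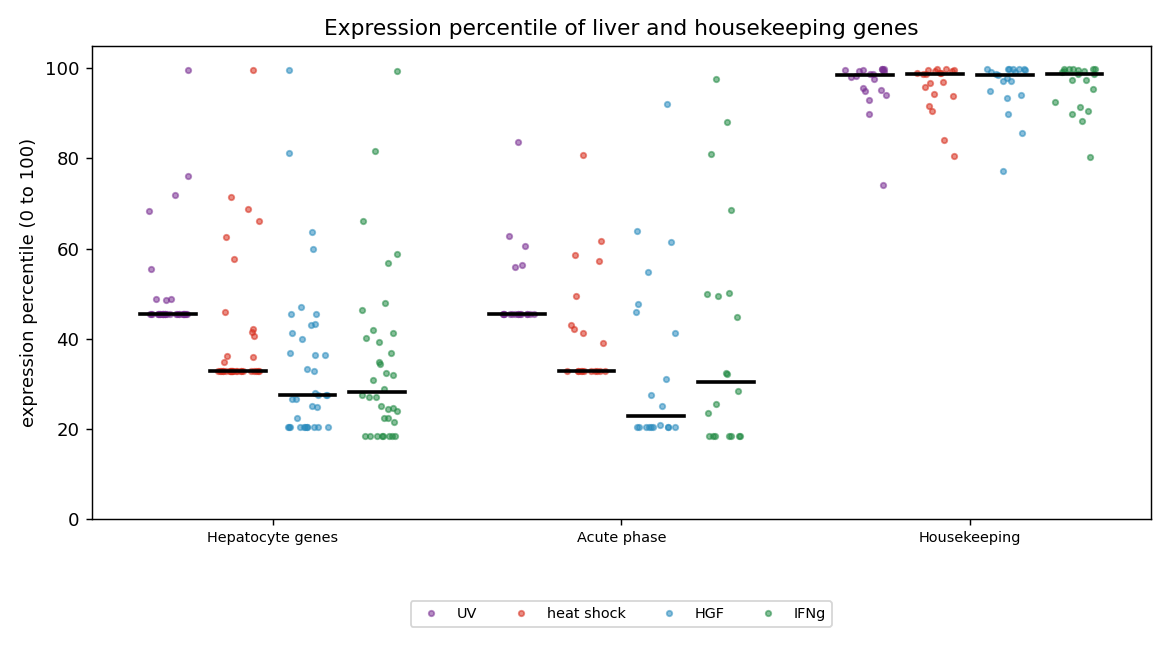
Expression percentile (y axis) of each gene (points) in the hepatocyte, acute phase and housekeeping lists (x axis) for the 4 treatments, with black bars at the list medians. Hepatocyte medians lie between 27.5 and 45.5, and housekeeping medians between 98.5 and 98.7.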

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

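Alternatives on GC content, the log2 rank scale, 5 and 20 points, deposited floors, re-ranking, 2-fold rank, 50 and 200 nt, the 5000 highest peaks and models with peaks in all 4 were chosen after seeing the data. The others were planned before, but their values in percentile or score-rank points (15, 50, 60 and 90) were set after the table had been seen. Not run were a pseudocount of 0.1 and other scaling factors (no amounts), 50% overlap (positions only), a 100 nt stop window and motif variants (no sequence of the table's build), and centring, which leaves ranks as they are. No paired analysis was possible because each group held 1 library. Depth is unknown, so what it limits cannot be stated. Of the values recomputed, 595 kept their call, or stayed within the interval or within 1.5 times; the rest follow. Unless the alternative itself sets a looser or stricter bound, the cause was not tested.

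Among peaks at or above the median score of their treatment, the transcript start share was 7.93% (UV), 1.80% (HGF) and 0.772% (IFNg). The stop codon share was then 31.2% (UV), 30.2% (heat shock), 33.96% (HGF) and 31.96% (IFNg). The coding sequence share was then 37.5% (UV), 38.9% (heat shock), 41.9% (HGF) and 43.96% (IFNg). The 3' UTR share was then 20.6% (UV), 19.5% (heat shock) and 22% (IFNg). Among the 5000 highest peaks, the transcript start share was 7.14% (UV) and 2.04% (HGF). The stop codon share was then 32.3% (UV), 30.1% (heat shock) and 33.3% (HGF). The coding sequence share was then 37.8% (UV), 39.1% (heat shock) and 42.3% (HGF). The 3' UTR share was then 20.04% (UV) and 19.6% (heat shock). In gene models with peaks in all 4, the transcript start share was 5.34% (UV), 4.64% (heat shock) and 2.08% (HGF). The stop codon share was then 22.9% (UV), 24.6% (heat shock) and 25.7% (HGF). The coding sequence share was then 46.5% (UV), 46.5% (heat shock) and 48.6% (HGF). The 3' UTR share was then 22.6% (UV), 21.8% (heat shock) and 21.8% (HGF).

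Peaks at or above the median score over all treatments numbered 8220 (UV), 5257 (heat shock), 3774 (HGF) and 1500 (IFNg), with 847 sites in all 4. At 50 points, sites higher and lower in score rank numbered 5 and 4 (UV), 7 and 3 (heat shock), 9 and 16 (HGF) and 23 and 41 (IFNg). At 15 points they numbered 235 and 220 (UV), 232 and 234 (heat shock), 218 and 240 (HGF) and 385 and 400 (IFNg). Against the median of the others they numbered 456 and 462 (UV), 454 and 459 (heat shock), 458 and 453 (HGF) and 585 and 597 (IFNg).

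Gene models higher and lower in expression, with the filter at 90, numbered 18 and 26 (UV), 9 and 103 (heat shock), 9 and 20 (HGF) and 78 and 66 (IFNg). Against the median of the other 3, the counts were 1372 and 1664 (UV), 1896 and 2141 (heat shock), 1640 and 1382 (HGF) and 1938 and 1938 (IFNg). At 5 points, the counts were 606 and 690 (UV), 1198 and 1394 (heat shock), 626 and 678 (HGF) and 1033 and 1386 (IFNg). At 20 points, they were 26 and 26 (UV), 44 and 54 (heat shock), 30 and 17 (HGF) and 127 and 27 (IFNg). With deposited floors, the counts that moved were 772 lower (heat shock), 398 lower (HGF) and 657 lower (IFNg). After re-ranking above the floor, they were 469 lower (UV), 893 and 1068 (heat shock), 384 and 505 (HGF) and 718 and 984 (IFNg). For a 2-fold rank difference, they were 67 and 30 (UV), 102 and 123 (heat shock), 76 and 38 (HGF) and 92 lower (IFNg). With GC correction, they were 181 and 189 (heat shock), 125 higher (HGF) and 260 and 200 (IFNg).

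For list shifts, a value is given where the list no longer stood apart from random lists (lost) or newly did (gained); a lost call can have the other sign. With unmatched random lists, lost were IFNg response -1.93 (UV), proliferation 1.88 (UV) and -2.81 (IFNg), histones -0.949 (UV), -0.940 (heat shock) and 1.61 (IFNg). Without the filter, lost were acute phase 0 (IFNg), histones -0.573 (heat shock), blood cell 0 (heat shock), cholangiocyte 0 (HGF). Under GC correction, lost were immediate early -1.72 (heat shock) and 1.48 (IFNg), MET-ERK -2.24 (heat shock), proliferation 1.87 (UV) and -1.34 (IFNg), histones -0.259 (UV), 1.17 (heat shock) and 0.334 (IFNg). Under GC correction, also lost were blood cell -8.93 (heat shock), cholangiocyte 6.02 (HGF). Under GC correction, gained were heat shock genes 2.90 (heat shock), hepatocyte 9.62 (UV), 14.8 (heat shock), -14.8 (HGF) and -9.62 (IFNg), unfolded protein 3.18 (IFNg). On the log2 rank scale, lost were IFNg response -0.15 (UV), MET-ERK -0.20 (heat shock), histones -0.58 (heat shock), cholangiocyte 0.47 (HGF). On the log2 rank scale, gained were heat shock genes 0.77 (heat shock) and -0.56 (IFNg), immediate early -0.28 (UV), proliferation 0.63 (heat shock) and -0.59 (HGF), histones 0.58 (HGF). On the log2 rank scale, also gained were blood cell 0.77 (HGF). Against UV alone, lost were IFNg response -0.374 (heat shock), DNA damage -1.64 (heat shock) and 4.17 (IFNg), MET-ERK -1.28 (heat shock), acute phase 14.1 (IFNg). Against UV alone, also lost were histones 0.0251 (heat shock), blood cell -12.6 (heat shock), cholangiocyte 10.6 (HGF). Against UV alone, gained were histones 0.546 (HGF). Against heat shock alone, lost were IFNg response 0.374 (UV), type I interferon -0.343 (UV), proliferation 0.0270 (UV), histones -0.0251 (UV). Against heat shock alone, also lost were cholangiocyte 11.7 (HGF). Against heat shock alone, gained were immediate early 4.60 (UV) and 6.24 (HGF). Against HGF alone, lost were IFNg response -0.0733 (UV) and -2.09 (heat shock), type I interferon 0.548 (UV), DNA damage -3.92 (heat shock) and 0.286 (IFNg), MET-ERK -3.58 (heat shock). Against HGF alone, also lost were proliferation 1.20 (UV), histones -0.546 (UV) and -0.694 (heat shock), blood cell -16.1 (heat shock). Against HGF alone, gained were unfolded protein 1.36 (IFNg). Against IFNg alone, lost were blood cell -16.5 (heat shock), cholangiocyte 1.87 (HGF). Against IFNg alone, gained were IFNg response -24.6 (HGF), type I interferon -18.6 (heat shock) and -21.9 (HGF), immediate early -4.67 (UV) and -3.32 (HGF), MET-ERK -9.64 (UV) and -6.24 (HGF). Against IFNg alone, also gained were acute phase -14.1 (UV), -17 (heat shock) and -20.8 (HGF), unfolded protein -1.36 (HGF), proliferation 2.98 (heat shock) and 1.05 (HGF), histones -0.428 (HGF).

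Of list score-rank shifts, calls lost were immediate early -5.49 (UV against heat shock), immediate early -18.8 (UV against HGF), immediate early 5.49 (heat shock against UV), immediate early 18.8 (HGF against UV). Calls gained were IFNg response -31.1 (HGF against IFNg), IFNg response 31.1 (IFNg against HGF), DNA damage -34.8 (UV against IFNg), DNA damage 34.8 (IFNg against UV). The opposite direction was reached by immediate early -21.98 (HGF against IFNg). The correlation of score-rank and expression shifts was 0.0999 (UV), 0.298 (heat shock), 0.108 (HGF) and 0.303 (IFNg) at a mean percentile of 90 or more. It was -0.119 (UV), -0.0554 (heat shock), -0.0613 (HGF) and 0.0382 (IFNg) with GC correction. The sign turned for UV in the former and for heat shock and HGF in the latter.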

Other observations

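The tests on hepatocyte genes, the test on the position of start peaks and every GC correction were chosen after those results were seen. GC-corrected values of top-ranked lists, such as proliferation, histone and housekeeping genes, carry the limit given with the methods. Proliferation genes (31) shifted by 1.88 points after UV (percentile 99.9), 1.18 after heat shock (97.0), -1.20 after HGF (2.54) and -2.81 after IFNg (0.210). With GC correction they shifted by 1.87 (95.8), -0.486 (34.8), 0.779 (51.8) and -1.34 (32.9) in that order, none standing apart. On the log2 rank scale the heat shock and HGF values stood apart, at 0.63 (99.1) and -0.59 (0.350), and the UV call was also lost against heat shock alone (0.0270) and HGF alone (1.20). Replication-dependent histones (16 genes) shifted by -0.949, -0.940, 0.517 and 1.61 points in the same order (0.150, 1.60, 97.3 and 99.99), and with GC correction none of the 4 stood apart. The histone calls after UV and heat shock were also lost against each other alone (-0.0251 and 0.0251) and against HGF alone (-0.546 and -0.694), and both those and the IFNg call, like the proliferation calls, were lost with unmatched random lists. Unfolded protein response genes shifted by 0.239, 0.295, -0.517 and 0.206 points (53.7, 57.1, 31.4 and 73.6). With GC correction they stood apart after IFNg, at 3.18 (99.1), where 5 of the 22 lay, uncorrected, at least 10 points above all other treatments, and the UV, heat shock and HGF values were -1.12, -1.06 and -0.0608. Cholesterol synthesis genes shifted by -1.77, -1.39, 1.89 and 1.66 (9.57, 17.8, 91.0 and 85.1), and with GC correction by -0.293, 2.29, 0.797 and -1.44 (32.6, 95.8, 60.9 and 31.7). Housekeeping genes shifted by at most 0.0251 points, and with GC correction by up to 1.66 (90.4, after UV), never standing apart. Among acute phase genes, 5 passed the filter, and they shifted by 14.1 points after IFNg (98.96), -3.46 after UV (17.3), -2.37 after heat shock (22.6) and 2.37 after HGF (77.2). The IFNg call was lost against UV alone (14.1) and without the filter (0). Complement C3, a component of that list chosen after its values were seen, stood at 97.8 after IFNg and between 80.8 and 92.2 elsewhere, and CFB at 88.1 and between 60.5 and 63.9. Markers of other cell types that passed the filter numbered 2 for blood cells, 8 for fibroblasts and endothelium, and 5 for cholangiocytes. The blood-cell pair was CD68, a macrophage marker, and HBB, an erythroid globin, and it shifted by -3.50, -16.1, 11.2 and 11.6 points after UV, heat shock, HGF and IFNg (22.8, 1.59, 93.5 and 89.7). Cholangiocyte markers shifted by 0.1003, -9.80, 11.1 and 0.0309 (49.2, 3.87, 98.2 and 58.2), and fibroblast and endothelial markers by 1.38, -2.18, -1.42 and 2.18 (71.7, 22.1, 30.7 and 80.6). With GC correction the blood-cell value after heat shock was -8.93 (4.36) and the cholangiocyte value after HGF 6.02 (97.475), neither standing apart. Both calls were also lost without the filter (0) and against each other treatment alone, though sizes mostly stayed near the main ones. They were -12.6, -16.1 and -16.5 for the blood-cell pair against UV, HGF and IFNg, and 10.6, 11.7 and 1.87 for cholangiocyte markers against UV, heat shock and IFNg. The 5 hepatocyte genes that passed shifted by 0.0347, 0.1003, -2.43 and 2.43 (48.7, 49.8, 22.1 and 78.7), and with GC correction all 4 stood apart, at 9.62, 14.8, -14.8 and -9.62. As the uncorrected medians were small, these corrected values cannot be told apart from the amounts subtracted. In peak numbers, 18 of 22 cholesterol synthesis genes had a peak after UV against 13 in matched random lists (98.1), 6 of 16 histones after UV against 11 (1.07), and 12 of 22 unfolded protein response genes after IFNg against 8 (97.51).

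Hepatocyte genes lay near the floor in cultures labelled as a hepatocarcinoma line. Loss of abundant transcripts in the authors' processing is argued against by the housekeeping list, whose lowest median over the 4 treatments was 98.5. A candidate explanation is that the cultures were not hepatocyte-like. The acute phase list, chosen as another liver list, had a highest median of 45.5. That value is itself the UV floor, and CPS1 at 99.4 to 99.7 goes the other way. As a second liver list, it repeats the pattern and cannot tell this explanation from a mislabelled column. A mislabelled culture or column was not tested, because no other line's marker list had been fixed.

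UV and heat shock stood apart from HGF and IFNg in expression rank. Unequal depth at the low end is argued against as the whole reason. Among gene models with a mean percentile of 90 or more, the lower correlation within pairs exceeded the highest across pairs by 0.361. A contribution among lower-ranked models stays open. The floors divided the same way, at 45.5 and 32.7 for UV and heat shock against 20.4 and 18.4 for HGF and IFNg. GC content bias may account for part of the split, with a rho of -0.717, and GC correction reduced the same gap over all gene models from 0.102 to 0.0437 without closing it. Among models with a mean percentile of 90 or more, a correction fitted within them reduced it from 0.367 to 0.221, while the one fitted over all models widened it to 0.479, so GC as the whole reason stays open. Gene length stays open, with a rho of 0.261 with genomic span that falls between the bounds set beforehand, and so does a shared response to stress, which was not tested and cannot be told apart from a batch that the labels do not give.

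Peaks near the transcript start took a larger share after UV and heat shock than after HGF and IFNg. The number of peaks called is argued against as the whole reason. With the 5000 highest peaks from each treatment, the lower share of the former pair was 3.50 times the higher of the latter. That ratio also reflects selection by score. HGF start peaks had a median score of 2.71, against 3.23 in coding sequence, and their share fell from 3.85% to 2.04%. Different genes carrying peaks is argued against as the whole reason, with a ratio of 2.23 in gene models with a peak in all 4. Lower coverage of transcript starts in the HGF and IFNg libraries may contribute, since matched start peaks lay 11 nt further in after HGF than after heat shock, against -1 nt in coding sequence, and 7.5 nt further in after IFNg, although IFNg start peaks lay -1 nt from those of HGF while their share was lower. A biological difference in methylation or in cap-adjacent modification was not tested and remains open, as the IP and input coverage were not used here.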
